A study of Arabidopsis thaliana with 9 samples.

How the data were processed

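Gene expression was measured by RNA sequencing of total RNA extracted with Trizol from 9 libraries of Arabidopsis thaliana Col-0. The labels place 3 libraries in a male group (stamens), 3 in a female group (gynoecium) and 3 in leaf, and give leaves and immature floral buds as the source material. The labels do not say whether the libraries of a group come from separate plants, so the spread between replicates may be smaller than that between plants. Same-numbered libraries of different groups are not said to share a plant or a day.

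The deposited count table holds whole-number counts of reads per gene made by the authors, whose notes name Bowtie2 2.2.3, HISAT2 2.1.0, TopHat2 and HTSeq 0.6.0 with the TAIR10 genome. The notes give no order or role for these tools, and no read filter, strand setting or annotation release. The table lists 32833 loci, of which 24400 had a count in some library and 8433 had none. The deposited FPKM table lists the 24400 loci with a count. At each locus, the ratio of count to FPKM was checked to scale with the library's total count alone (relative difference at most 1.3e-14). Whether the remaining constant of each locus is a gene length was not checked. The files name genes by locus, and symbols, descriptions, gene overlap and neighbours were taken from the TAIR10.1 assembly's annotation, in which 32548 of 32833 loci were matched, 10804 with a symbol and 31554 with a description. Coordinates are not printed, since the deposited values rest on TAIR10.

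Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr by group, which left 20827, and libraries were scaled with TMM factors (0.955 to 0.966 in stamens, 1.272 to 1.279 in gynoecium, 0.815 to 0.817 in leaf). A quasi-likelihood model with robust estimates and 1 mean per group was fitted to all 9 libraries. Male was compared with female, male with leaf and female with leaf, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Total counts ran from 16042169 to 18756860 per library, and 3 counts correspond to 0.126 to 0.229 CPM. A fold against a group at 0 in all libraries was computed against 3 counts per library and is a lower bound. A group with 1 to 3 counts is given as a ratio with its exact 95% interval, and intervals and floors cover counting error only.

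Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, correlation preset at 0.01), with adjustment over the 19 lists. The lists hold 398 entries, of which 377 were kept and 21 were left out because the annotation did not pair the locus with the listed symbol. Families were formed from words in gene descriptions, and the 31 with at least 5 tested genes were tested in the same way. The tests, lists, family words, alternatives and the rule for named genes were chosen before the data were examined, except those stated to have been added later. That rule names, per comparison, the 6 called genes with a symbol that changed most in each direction among those with at least 20 CPM and no overlap between groups. It also names up to 3 called members per list and direction with the uncalled member of highest level, a fixed set of 13 markers in each comparison, the 5 genes that stand out most in each tissue, and the leading members of called families. The text gives values for a selection of these.

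Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, intervals and figures. The edgeR steps were tested on simulated data with 50 genes changed at each of 4 sizes. In the comparison of male with female, 31, 44, 50 and 50 were recovered at 1.25-fold, 1.5-fold, 2-fold and 4-fold, and 11 of 19928 unchanged genes were called. A planted list was called, and of 18 random lists camera called 1 with the preset correlation and 0 with an estimated one. Nearly all simulated genes were unchanged and all were drawn independently. Most genes tested in the data were called, so these rates may not hold for the data.

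Alternatives were other scalings (DESeq2 size factors, upper quartile), DESeq2 1.42.0, limma-voom, limma on log2 of FPKM plus 1 or 0.1, other filters, the replicate number as a block, the libraries of a comparison alone, each replicate left out, a test against a 2-fold change, and for lists an estimated correlation and fry. Library totals alone, a fit without organelle genes and a fit without genes that overlap another gene model were added after the data were seen. Other splits of the libraries were counted for each test. Of the kept list genes, 24 had no count in any library, 5 of them with over 80% of their exon bases in another gene model.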

Results

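Gene expression was profiled by RNA sequencing in 3 tissues of Arabidopsis thaliana Col-0, the standard laboratory accession of this plant. Stamens, the pollen-bearing organs, make up the male group, and the gynoecium, the organ that encloses the ovules, makes up the female group. Leaf is the vegetative tissue, and each group holds 3 libraries. Total counts per library were 17887733, 17776983 and 16916596 in male replicates 1 to 3, 18756860, 17248590 and 18086920 in female replicates 1 to 3, and 16042169, 17204372 and 17205304 in leaf replicates 1 to 3. Stamen libraries had counts for 22194 ± 92.4 genes (mean ± SD, n = 3), gynoecium libraries for 19501 ± 39.5 and leaf libraries for 18375 ± 32.9. Chloroplast genes took 5.90 ± 0.043% of the counts in leaf, 0.928 ± 0.007% in gynoecium and 0.906 ± 0.005% in stamens. The 10 most abundant genes of each library took 11.9 ± 0.151% of the counts in leaf, 6.0 ± 0.02% in stamens and 3.45 ± 0.016% in gynoecium.

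Levels are given as CPM, read counts relative to the TMM-scaled library size, as mean ± SD of the 3 libraries of a group, and each locus is given with its symbol at first mention. A count of 0 in a library allows a level of up to 0.126 to 0.229 CPM, the value of 3 counts. Adjusted p-values come from edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment over the 20827 genes tested. Of the single genes named, 71 were called between stamens and gynoecium, 75 between stamens and leaf and 58 between gynoecium and leaf. They were picked for being called, and in part for groups that do not overlap, so these counts say nothing on how often genes differ.

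Libraries of the same tissue resembled each other far more than libraries of different tissues did, across genes, which are not independent replicates. Spearman correlations over the genes tested ran from 0.9961 to 0.9982 within a tissue. They ran from 0.731 to 0.7325 between stamens and gynoecium, from 0.7449 to 0.7481 between gynoecium and leaf, and from 0.6282 to 0.6352 between stamens and leaf. None of the pairs of libraries was identical, and counts of same-tissue pairs differed by 1.77 to 3.10 times what counting error alone gives (chi-square per degree of freedom). The biological coefficient of variation over all groups was 3.62%, and the labels do not say whether the libraries of a tissue come from separate plants.

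**Figure D1:**
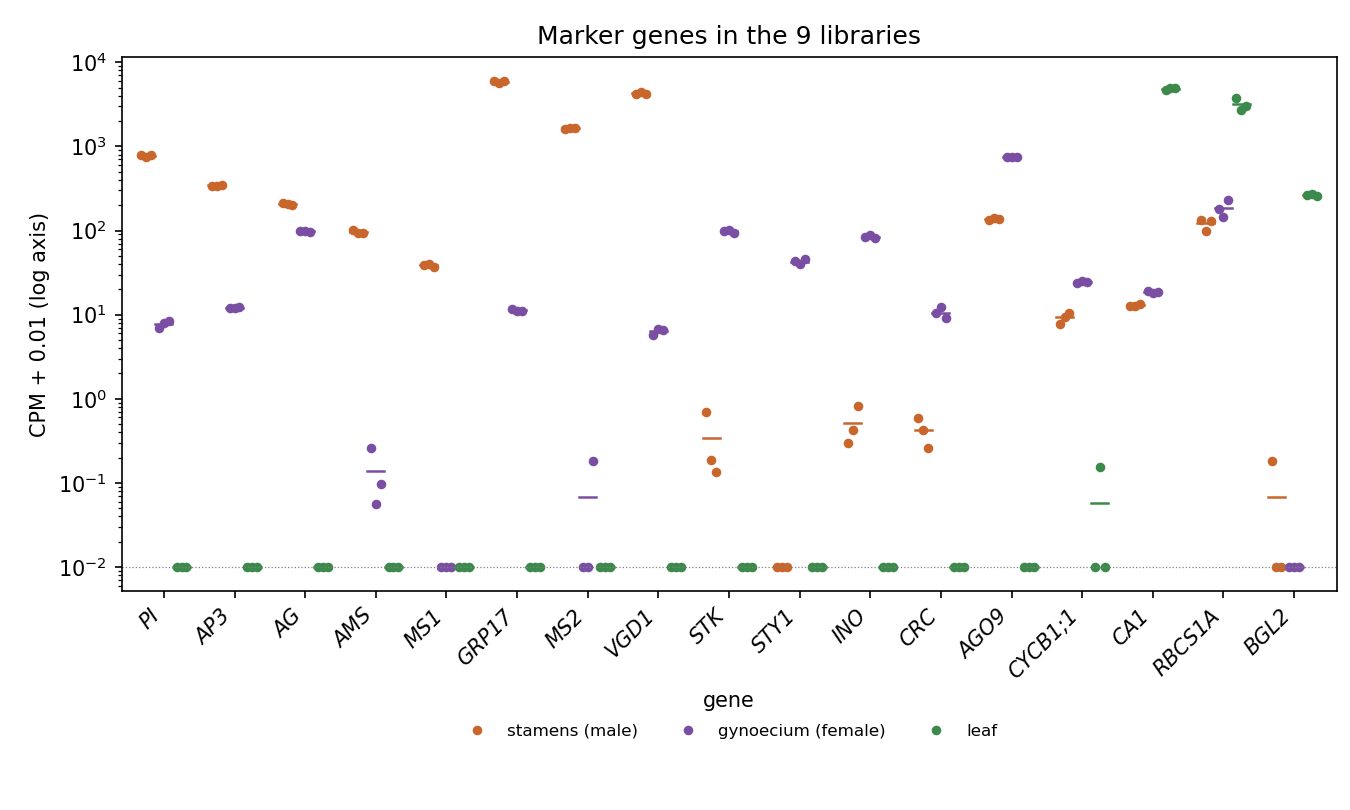
Level of 17 marker genes in each of the 9 libraries, as CPM plus 0.01 on a log axis, with 1 point per library and a bar at each group's mean; points on the dotted line are counts of 0. PI, AP3, AMS, MS1, GRP17, MS2 and VGD1 stand highest in stamens, STK, STY1, INO, CRC and AGO9 in gynoecium, and CA1, RBCS1A and BGL2 in leaf.

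The comparison of male with female libraries asks which genes differ between the organs that carry pollen and ovules, the contrast named by the series design. Most carpel and ovule genes tested were higher in gynoecia. PI (AT5G20240) and AP3 (AT3G54340), the B-class genes that specify petals and stamens, stood at 775 ± 28.8 and 343 ± 0.685 CPM in stamens against 7.75 ± 0.683 and 12.04 ± 0.185 CPM in gynoecia. The ovule identity gene STK (AT4G09960) stood at 98.2 ± 4.05 CPM in gynoecia against 0.332 ± 0.316 CPM in stamens, a 296-fold difference (adjusted p = 3.26e-47). Its stamen counts were 12, 3 and 2, and without male replicate 1 its log2 change went from -8.16 to -9.27. All 26 cell cycle genes tested were lower in stamens, and all tested members of the pollen wall, mature pollen and male germline lists were higher.

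Pollen genes were higher in stamens throughout the lists tested. All 22 genes tested for the pollen wall were higher in stamens, with a median log2 change of 8.70, or 8.53 with groups at 0 set to their bound (camera adjusted p = 4.8e-08). QRT3 (AT4G20050), which helps to separate the microspores of a tetrad, had 466 ± 7.55 CPM in stamens and no count in gynoecia, a difference of at least 3567-fold. MS2 (AT3G11980), a fatty acyl reductase of sporopollenin synthesis, had 83252 counts in the stamen libraries against 4 in the gynoecium libraries, all 4 in female replicate 3. The callose synthase CALS5 (AT2G13680), needed for the microspore wall, was at least 464-fold higher. All 24 genes of mature pollen and the pollen tube were higher as well, with a median of 11.21, or 7.23 at the bound (camera adjusted p = 6.04e-09). Among these, the proton pump AHA9 (AT1G80660) had 1700.0 ± 44.95 CPM in stamens and the calcium pump ACA9 (AT3G21180) 247 ± 4.02 CPM, both against 0 counts in gynoecia. The pectin methylesterase gene VGDH1 (AT2G47030) had 533 ± 19.1 CPM against 0 counts, though reads of its near-identical neighbour VGD1 may be shared with it. All 8 genes tested for sperm cells and the male germline were higher, with a median of 9.43, or 5.21 at the bound (camera adjusted p = 0.000517). MGH3 (AT1G19890), the histone H3 of sperm cells, stood at 10.1 ± 1.61 CPM, TIP5;1 (AT3G47440), a pollen aquaporin, at 13.7 ± 0.880 CPM, and DAZ1 (AT2G17180), a zinc finger gene of the male germline, at 6.73 ± 0.392 CPM. None of these 3 had a count in gynoecia. With an estimated correlation the calls of these lists held, at adjusted p = 0.0129, 0.0191 and 0.0253.

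Of 18 regulators of anther and tapetum tested, 12 were higher in stamens and 6 lower (median 4.71, or 3.47 at the bound), and the list did not pass its test (camera adjusted p = 0.0938). It did with library totals (0.0172) and without genes that overlap another gene model (0.0133), within 0.0133 to 0.413 over the camera alternatives. The tapetum regulators MS1 (AT5G22260) and AMS (AT2G16910) were higher: MS1 had 38.4 ± 1.32 CPM against no count, and AMS was 747-fold higher (SE of log2 0.363, adjusted p = 4.27e-53), a log2 change of 9.44 that went to 10.35 without female replicate 1. The gynoecium counts of AMS were 6, 1 and 2, and the prior count narrows its SE. NST1 (AT2G46770), which directs wall thickening of the anther endothecium, was at least 241-fold higher, and DYT1 (AT4G21330), another tapetum regulator, at least 11.5-fold. SPL (AT4G27330), which starts spore formation, was 58.2-fold higher. The receptor kinase gene SERK2 (AT1G34210) was 2.93-fold lower, at 32.7 ± 1.66 against 95.8 ± 0.839 CPM.

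Genes of the gynoecium and its ovules went the other way. Of 19 gynoecium patterning genes, 17 were lower in stamens and 2, ETT and NGA4, were higher (median -4.64, or -3.62 at the bound, camera adjusted p = 1.8e-06). STY1 (AT3G51060), which promotes style development, had 42.8 ± 2.94 CPM in gynoecia and no count in stamens. The fruit valve margin genes SHP1 (AT3G58780) and SHP2 (AT2G42830) were 112-fold and at least 12.3-fold higher in gynoecia, and 56.7% of the exon bases of SHP2 are shared with another gene model, which may limit its counts. The log2 change of SHP1 went from -6.74 to -7.80 without male replicate 1. The carpel gene CRC (AT1G69180) stood at 10.6 ± 1.59 CPM in gynoecia against 0.413 ± 0.166. ETT (AT2G33860), an auxin response factor of carpel patterning, was 1.37-fold higher in stamens, a call that ended with library totals in place of TMM (adjusted p = 0.307) and with FPKM (0.425 to 0.44), over a range of 7.59e-22 to 0.44 outside the test against a 2-fold change. Of 14 ovule and integument genes, 12 were lower in stamens and 2 higher (median -2.60, camera adjusted p = 0.000292). The outer integument gene INO (AT1G23420) had 84.4 ± 3.65 CPM in gynoecia against 0.501 ± 0.267, and the boundary gene CUC3 (AT1G76420) was at least 33.2-fold lower in stamens. WUS (AT2G17950), a stem cell gene, was among the 2 members that were higher, at 19.4 ± 1.02 CPM in stamens against 1.39 ± 0.382. The calls of both lists held with an estimated correlation (adjusted p = 0.0129 and 0.0215). Only 6 of 23 female gametophyte genes had enough counts to be tested, of which 4 were higher in stamens, 1 lower and 1 not called (median 3.10, or 0.97 at the bound, camera adjusted p = 0.186). FWA (AT4G25530), a homeodomain gene known from the central cell, had 3.47 ± 0.922 CPM in stamens and no count in gynoecia, while AGL80 (AT5G48670), a MADS-box gene of the central cell, was 2.17-fold lower in stamens.

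Cell division genes were higher in gynoecia throughout. All 26 genes of the cell cycle and DNA replication were lower in stamens, with a median log2 change of -1.96 (camera adjusted p = 6.83e-08, and 0.0129 with an estimated correlation). The B-type cyclin CYCB2;2 (AT4G35620) was 56.2-fold lower and the A-type cyclin CYCA1;1 (AT1G44110) 12-fold lower. Meiosis genes divided: of 30 tested, 12 were higher in stamens, 13 lower and 5 not called, with 11 higher when adjusted over the list alone. Their median was -0.10, their mean 0.78, and the camera direction was down (adjusted p = 0.744), so median and mean differ in sign. TDM1 (AT4G20900), which ends meiosis, had 8.91 ± 0.563 CPM in stamens against no count, and the crossover helicase gene RCK (AT3G27730) was 8.54-fold lower in stamens. DMC1 (AT3G22880), the meiotic recombinase, stood at 7.69 ± 0.819 CPM in stamens and 7.80 ± 0.27 in gynoecia and was not called (adjusted p = 0.882). It was called lower with FPKM (0.00557 to 0.0439) and with library totals (0.00235), within 0.00235 to 1 over its alternatives.

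The floral homeotic list held 5 genes that were higher and 7 that were lower in stamens (median -0.35, mean -0.17, camera direction down, adjusted p = 0.42). AG (AT4G18960), the C-class gene of stamens and carpels, was 2.09-fold higher in stamens. SUP (AT3G23130), which keeps B-class activity out of the centre of the flower, was 16.6-fold lower, and SEP4 (AT2G03710), an E-class gene, 9.07-fold lower. LFY (AT5G61850), the meristem identity gene, was at least 4.90-fold lower. Among 30 genes of DNA methylation, small RNA and Polycomb, 11 were higher, 15 lower and 4 not called (median -0.23, camera adjusted p = 0.183). That list was called without genes that overlap another gene model (0.0361, within 0.0361 to 0.38 over the camera alternatives). AGO9 (AT5G21150), an Argonaute of the ovule, stood at 741 ± 1.97 CPM in gynoecia against 137 ± 3.70 in stamens, and RDR2 (AT4G11130), an RNA-dependent RNA polymerase, was 6.45-fold lower in stamens. The demethylase gene DML3 (AT4G34060) was 35.6-fold higher in stamens, DCL3 (AT3G43920), a Dicer of the small RNA pathway, 4.28-fold higher, and the Polycomb gene MEA (AT1G02580) at least 18.6-fold higher.

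Hormone lists were mixed. The gibberellin list held 2 genes that were higher, 9 lower and 1 not called (median -0.93, mean -0.15, camera adjusted p = 0.0376). That call was lost with an estimated correlation (adjusted p = 0.111), without male replicate 1 (0.0555) and with library totals (0.0676), within 0.0286 to 0.111 over the camera alternatives, and fry gave the opposite direction, up (0.000126). GA3OX3 (AT4G21690), a late step of gibberellin synthesis, had 13.8 ± 0.549 CPM in stamens and no count in gynoecia, while the DELLA repressor gene RGL3 (AT5G17490) was 2.86-fold lower. Auxin genes counted 7 higher and 11 lower (median -1.36, mean 0.05, camera direction down, adjusted p = 0.183): ARF17 (AT1G77850), an auxin response factor of pollen wall formation, was 44.7-fold higher and YUC2 (AT4G13260), an auxin synthesis gene, at least 199-fold higher. Jasmonate genes counted 4 higher, 9 lower and 7 not called (median -0.13, mean 0.025, camera direction down, adjusted p = 0.183). JAR1 (AT2G46370), which makes the active jasmonate, was 11.9-fold higher and the storage protein gene VSP1 (AT5G24780) 7.05-fold lower, while the lipoxygenase gene LOX2 (AT3G45140) stood at 164 ± 9.43 and 165 ± 4.01 CPM and was not called (adjusted p = 0.867). LOX2 was called lower with upper quartile factors (7.82e-05), FPKM (5.17e-06 to 1.01e-05) and library totals (3.43e-15), within 3.43e-15 to 0.985 outside the test against a 2-fold change.

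Among 37 light harvesting and photosystem genes, 12 were higher in stamens, 20 lower and 5 not called (median -0.23, camera adjusted p = 0.183, but 0.0382 with library totals, within 0.0382 to 0.72 over the camera alternatives). PSBO2 (AT3G50820), of the oxygen-evolving complex, was 18.1-fold higher in stamens, and LHCB3 (AT5G54270) stood at 138 ± 5.16 and 141 ± 7.94 CPM and was not called (adjusted p = 0.359). LHCB3 was called lower with upper quartile factors (9.3e-05), FPKM (9.81e-06 to 2.11e-05) and library totals (1.07e-13), within 1.07e-13 to 0.771 outside the test against a 2-fold change. The Calvin cycle list had 4 higher, 9 lower and 3 not called (median -0.20, camera adjusted p = 0.207). HCEF1 (AT3G54050), a fructose bisphosphatase, was 1.85-fold higher. RBCS1A (AT1G67090), a Rubisco small subunit, was 1.52-fold lower (adjusted p = 0.0459), and its call ended without female replicate 1 (0.0877) or 3 (0.144), without leaf replicate 2 (0.0502) or 3 (0.0673), and without male replicate 1 (0.0688), 2 (0.134) or 3 (0.0751). It also ended with limma-voom (0.102) and with the libraries of both organs alone (0.0626), within a range of 0.000468 to 0.144 outside the test against a 2-fold change. Flavonoid genes counted 5 higher and 6 lower (median -0.43, camera adjusted p = 0.42): CHS (AT5G13930), the entry enzyme of the pathway, stood at 1261 ± 10.1 CPM in stamens against 316 ± 4.83, and MYB11 (AT3G62610), a flavonol regulator, had 2 counts in stamens against 392 in gynoecia, both in male replicate 2, a ratio of 143 (exact 95% interval 39.4 to 1190.0). Defence markers counted 3 higher, 6 lower and 3 not called (median -0.07, mean 0.51, camera direction down, adjusted p = 0.228). EDS1 (AT3G48090), an immune regulator, was 4.47-fold lower, and PAD3 (AT3G26830), of camalexin synthesis, at least 26.3-fold higher. Housekeeping genes counted 4 higher, 2 lower and 1 not called (median 0.16, camera adjusted p = 0.995), which turned to 2 higher and 3 lower with upper quartile factors and to 1 higher and 5 lower with library totals. ACT7 (AT5G09810) was 1.90-fold lower, UBQ10 (AT4G05320) 2.05-fold higher, and UBC9 (AT4G27960) stood at 22.2 ± 1.13 and 24.0 ± 1.35 CPM (adjusted p = 0.152). UBC9 was called lower with upper quartile factors (0.00107), FPKM (2.75e-05 to 4.84e-05) and library totals (5.91e-09), within 5.91e-09 to 0.448 outside the test against a 2-fold change.

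In total 17773 of 20827 genes (85.3%) differed between stamens and gynoecium by edgeR, 9645 higher and 8128 lower in stamens, of which 5848 and 3811 by at least 2-fold. The largest changes among abundant genes with a symbol included the cytochrome P450 gene CYP705A24 (AT1G28430), at 836 ± 6.84 CPM in stamens and no count in gynoecia. The desaturase gene AT1G06080 had 61.7 ± 1.44 CPM in gynoecia and no count in stamens, the zinc finger gene IDD4 (AT2G02080) 59.97 ± 0.922, the AINTEGUMENTA-like gene AIL5 (AT5G57390) 38.6 ± 3.04 and the ferric reductase gene FRO8 (AT5G50160) 36.6 ± 1.43. The share of calls that were higher depends on the scaling: 54.3% with TMM and 39.8% with library totals, which moved the median of all genes by -0.37 on the log2 scale.

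The comparison of male libraries with leaf sets stamens against a vegetative organ. All tested pollen genes and most meiosis and floral homeotic genes were higher in stamens, and all tested photosynthesis and defence genes were higher in leaf. PI, AP3 and AG had no count in any leaf library and were at least 3540.0-fold, 1568-fold and 939-fold higher in stamens. GRP17 (AT5G07530), an oleosin-type protein of the pollen coat, had 5883 ± 156 CPM in stamens and no count in leaf, and VGD1 (AT2G47040), a pectin methylesterase of the pollen tube, 4293 ± 127 CPM and no count. The carbonic anhydrase gene CA1 (AT3G01500) went the other way, from 4864 ± 112 CPM in leaf to 12.8 ± 0.404 in stamens, 378-fold lower (SE of log2 0.0321, adjusted p = 1.1e-78).

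All 22 pollen wall genes, all 24 mature pollen genes and all 8 male germline genes tested were higher in stamens than in leaf. Their median log2 changes were 14.72, 11.24 and 9.43, or 9.76, 6.78 and 4.46 with groups at 0 set to their bound, and camera gave adjusted p = 2.27e-07, 7.66e-08 and 0.00143. With an estimated correlation the calls held (adjusted p = 0.0173, 0.0244 and 0.0383). A7 (AT4G28395), a tapetum lipid transfer protein, stood at 978 ± 61.1 CPM and MS2 at 1650.0 ± 30.4 CPM, both with no count in leaf. AHA9 had 85782 counts in stamens against 1 in leaf, in replicate 2, a ratio of 70000 (exact 95% interval 12600 to 2760000). Meiosis genes were higher in 26 of 30 cases, with 1 lower and 3 not called (median 4.24, or 3.05 at the bound, camera adjusted p = 0.000155, and 0.0173 with an estimated correlation). PS1 (AT1G34355) and JASON (AT1G06660), which set the spindles of the second division, had 34.9 ± 2.40 and 21.2 ± 0.296 CPM and no count in leaf. The meiotic cohesin gene SYN1 (AT5G05490) was at least 61.4-fold higher and DMC1 5.24-fold. SGO1 (AT3G10440), which protects centromere cohesion, stood at 14.9 ± 0.59 and 14.2 ± 1.16 CPM and was not called (adjusted p = 0.514). SGO1 was called higher with FPKM (0.00351 to 0.00472) and library totals (0.00437), within 0.00351 to 0.994 outside the test against a 2-fold change.

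Of 12 floral homeotic genes, 9 were higher, 1 lower and 2 not called (median 5.82, or 2.80 at the bound, camera adjusted p = 0.0181, and 0.104 with an estimated correlation, within 0.0161 to 0.104 over the camera alternatives). SEP4 was the lower one, at 2.67 ± 0.472 CPM against 80.8 ± 3.08 in leaf, and AP2 (AT4G36920), an A-class gene, stood at 22.1 ± 0.50 and 22.03 ± 0.598 CPM (adjusted p = 0.993). AP2 was called higher with FPKM (0.00116 to 0.0014) and library totals (0.0043), within 0.00116 to 0.999 outside the test against a 2-fold change. Anther and tapetum regulators were higher in 15 and lower in 3 of 18 (median 9.53, or 5.98 at the bound, camera adjusted p = 0.00158, and 0.186 with an estimated correlation, within 0.000701 to 0.186 over the camera alternatives). TGA10 (AT5G06839), a bZIP regulator of anthers, EMS1 (AT5G07280), the receptor kinase of tapetal fate, and AMS were at least 621-fold, 498-fold and 436-fold higher, whereas TPD1 (AT4G24972), the ligand of EMS1, was 6.09-fold lower. MS1, SPL and DYT1 had no count in leaf and were at least 176-fold, 127-fold and 6.84-fold higher.

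Gynoecium patterning genes counted 12 higher, 3 lower and 4 not called in stamens against leaf (median 2.18, or 1.53 at the bound, camera adjusted p = 0.22). NGA4 (AT4G01500), a style regulator, was at least 36.4-fold higher and FUL (AT5G60910), a fruit valve gene that leaves also express, 22.3-fold lower. CRC was at least 1.89-fold higher, and STK at least 1.52-fold, a call that ended with FPKM (adjusted p = 0.068 and 0.0749, within 1.31e-05 to 0.0749). The STK counts of stamens, 12, 3 and 2, stand above 3 in male replicate 1 alone, and without it the log2 change went from 5.62 to 4.51 (0.00722). Ovule genes counted 8 higher, 5 lower and 1 not called (median 2.51, or 0.465 at the bound, camera adjusted p = 0.809). WUS was at least 88.6-fold higher and BEL1 (AT5G41410), an integument gene that leaves also express, 13.8-fold lower. Of the 6 female gametophyte genes tested, 3 were higher and 3 lower (median 3.80, or 1.31 at the bound, camera adjusted p = 0.926): FWA was at least 15.8-fold higher and AGL62 (AT5G60440), an endosperm gene, 10.8-fold lower. Of 26 cell cycle genes, 15 were higher, 6 lower and 5 not called (median 0.42, camera adjusted p = 0.447). CYCB1;1 (AT4G37490), a mitotic cyclin, had 465 counts in stamens against 2 in leaf, both in replicate 2, a ratio of 190.0 (exact 95% interval 52.2 to 1570.0), the cytokinesis kinesin gene HIK (AT1G18370) was 1.88-fold lower, and MCM6 (AT5G44635), of the replicative helicase, stood at 11.8 ± 1.68 and 12.5 ± 0.809 CPM (adjusted p = 0.464).

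Photosynthesis and defence genes were lower in stamens without exception among those tested. All 37 light harvesting and photosystem genes were lower, with a median log2 change of -4.09 (camera adjusted p = 4.64e-14, and 0.104 with an estimated correlation, within 2.13e-16 to 0.104 over the camera alternatives), and chloroplast genes took 0.906% of the stamen counts against 5.90% in leaf. LHCB1.2 (AT1G29910) fell from 4905 ± 152 CPM in leaf to 154 ± 4.42 in stamens, though reads of its near-identical copies may be shared. PSAE-1 (AT4G28750) was 52.7-fold lower and PSAG (AT1G55670) 30.1-fold lower, with 61.4% of the exon bases of PSAG shared with another gene model. All 16 Calvin cycle genes were lower (median -4.37, camera adjusted p = 2.89e-08, and 0.0173 with an estimated correlation): RBCS1A was 26.1-fold lower and RBCS1B (AT5G38430) 598-fold, the latter with reads that near-identical copies may share. All 12 defence markers were lower (median -4.86, camera adjusted p = 2.67e-06, and 0.0173 with an estimated correlation). The salicylate marker PR1 (AT2G14610) and the jasmonate marker PDF1.2 (AT5G44420) had 102 ± 5.18 and 18.2 ± 1.43 CPM in leaf and no count in stamens, and PR2 (AT3G57260) had 10943 counts in leaf against 3, all in male replicate 1, a ratio of 4470 (exact 95% interval 1530 to 21700).

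Genes of DNA methylation, small RNA and Polycomb were higher in 25 of 30 cases, with 2 lower and 3 not called (median 1.74, camera adjusted p = 0.000728, and 0.0651 with an estimated correlation, within 0.000565 to 0.0651 over the camera alternatives). AGO9 and AGO5 (AT2G27880), an Argonaute of reproductive cells, had no count in leaf and were at least 625-fold and 161-fold higher. The demethylase gene DME (AT5G04560) was 1.3-fold lower, a call that ended with FPKM (adjusted p = 0.0517 to 0.0548, within 1.17e-14 to 0.0548 outside the test against a 2-fold change), and the methyltransferase gene MET1 (AT5G49160) stood at 21.1 ± 1.57 and 18.8 ± 0.962 CPM (adjusted p = 0.0626). MET1 was called higher with DESeq2 size factors (0.0418), FPKM (0.00284 to 0.00317) and library totals (2.7e-05). It was also called without female replicate 1 (0.0359), 2 (0.0343) or 3 (0.0312), leaf replicate 2 (0.039) or male replicate 3 (0.021), within 2.7e-05 to 0.214 outside the test against a 2-fold change. Flavonoid genes counted 6 higher, 3 lower and 2 not called (median 1.71, camera adjusted p = 0.475): CHS was 19.01-fold higher and the anthocyanin regulator PAP1 (AT1G56650) at least 46.3-fold lower. Auxin genes counted 10 higher, 5 lower and 3 not called (median 0.47, camera adjusted p = 0.834), with the carrier gene PIN8 (AT5G15100) at least 22.1-fold higher and PIN7 (AT1G23080) 10.8-fold lower. Jasmonate genes counted 7 higher, 10 lower and 3 not called (median -0.18, camera adjusted p = 0.149, but 0.0409 without genes that overlap another gene model, within 0.0409 to 0.26 over the camera alternatives), which turned to 9 higher and 8 lower with library totals. JAR1 was 4.88-fold higher, and AOC2 (AT3G25770), of jasmonate synthesis, 203-fold lower, with reads that its near-identical copy AOC1 may share. Gibberellin genes counted 6 higher, 5 lower and 1 not called (median 0.49, camera adjusted p = 0.92): GA3OX3 was at least 62.9-fold higher and the receptor gene GID1A (AT3G05120) 2.05-fold lower. Housekeeping genes counted 1 higher and 6 lower (median -0.63, camera adjusted p = 0.0283, and 0.104 with an estimated correlation, within 0.0257 to 0.104 over the camera alternatives): PP2AA3 (AT1G13320) was 1.47-fold higher and ACT2 (AT3G18780) 6.72-fold lower.

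Of 20827 genes tested, 18305 (87.9%) differed between stamens and leaf by edgeR, 10419 higher and 7886 lower in stamens, of which 6974 and 4946 by at least 2-fold. Among the largest changes, ATA27 (AT1G75940), a glycosyl hydrolase of the tapetum, had 5179 ± 77.7 CPM in stamens, the proton pump gene HA6 (AT2G07560) 4380.0 ± 113, the VANGUARD-like gene VGDH2 (AT3G62170) 1923 ± 31.8 and XTH3 (AT3G25050), a xyloglucan hydrolase, 3290.0 ± 23.6, all with no count in leaf. ACD6 (AT4G14400), a regulator of defence and cell death, had 2076 ± 75.2 CPM in leaf and no count in stamens, and the glucanase gene BG3 (AT3G57240) 165 ± 5.12 CPM. FRO8 had 203 ± 6.03 CPM in leaf and no count in stamens.

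The comparison of female libraries with leaf sets the gynoecium against the same vegetative organ. All tested gynoecium patterning and cell cycle genes and most ovule, meiosis and small RNA genes were higher in gynoecia, and all tested photosynthesis and defence genes were again higher in leaf. SEP2 (AT3G02310), an E-class floral gene, and AGO9 stood at 207 ± 5.53 and 741 ± 1.97 CPM in gynoecia and had no count in leaf, at least 944-fold and 3385-fold higher. STK and STY1 were at least 449-fold and 196-fold higher. CA1 was 264-fold lower in gynoecia, at 18.4 ± 0.514 CPM (SE of log2 0.0301, adjusted p = 2.47e-78).

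All 19 gynoecium patterning genes tested were higher in gynoecia than in leaf (median 8.92, or 4.72 at the bound, camera adjusted p = 7.37e-07). SHP1 was at least 100.1-fold higher, CRC at least 48.2-fold and SHP2 at least 10.0-fold. Of 14 ovule genes, 13 were higher and 1 lower (median 8.19, or 3.71 at the bound, camera adjusted p = 0.000398), with INO at least 385-fold higher. Of 12 homeotic genes, 11 were higher and SEP4 was 3.34-fold lower (median 6.47, or 3.56 at the bound, camera adjusted p = 0.000304). AG and SUP were at least 449-fold and 193-fold higher, and AP3 and PI at least 55.0-fold and 35.4-fold. All 26 cell cycle genes were higher (median 2.95, camera adjusted p = 2.56e-07): CYCB2;1 (AT2G17620), a mitotic cyclin, and AUR2 (AT2G25880), a mitotic kinase, were at least 30.2-fold and 29.1-fold higher, and CYCB1;1 had 1681 counts against 2, both in leaf replicate 2, a ratio of 501 (exact 95% interval 139 to 4140). Meiosis genes were higher in 24 of 30 cases, with 2 lower and 4 not called (median 3.08, or 2.82 at the bound, camera adjusted p = 3.58e-05), and DMC1 was 5.32-fold higher. Genes of DNA methylation, small RNA and Polycomb were higher in 24 of 30 cases, with 3 lower and 3 not called (median 1.51, camera adjusted p = 3.27e-05): AGO5 and RDR2 were at least 613-fold and 190-fold higher, and DML3 was 4.34-fold lower. With an estimated correlation the calls of these lists held, at adjusted p = 0.0131 for the gynoecium, cell cycle and meiosis lists, 0.0233 for ovule genes and 0.0275 for the other 2.

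Male development lists were mixed between gynoecium and leaf. Of 22 pollen wall genes, 12 were higher than in leaf, 2 lower and 8 not called (median 3.89, or 1.34 at the bound, camera adjusted p = 0.00398, and 0.0722 with an estimated correlation, within 0.00136 to 0.0722 over the camera alternatives). Some of these genes stood at small shares of their stamen level, 0.191% for GRP17 and 0.17% for A7, and carry-over of a single stamen tissue stays open. Of 18 anther and tapetum regulators, 10 were higher, 1 lower and 7 not called (median 1.105, or 1.045 at the bound, camera adjusted p = 0.0346, and 0.299 with an estimated correlation, within 0.0252 to 0.299 over the camera alternatives). That call also ended with library totals (0.206) and without genes that overlap another gene model (0.0956). EMS1 was at least 546-fold higher, at 120 ± 2.91 CPM, TPD1 was 3.87-fold lower, and SPL at least 2.18-fold higher at 0.478 ± 0.111 CPM. AMS passed the test at 0.128 ± 0.109 CPM against no count (adjusted p = 0.00831), below the level of 3 counts, and did not pass it without female replicate 1 (0.0634) or with FPKM plus 1 (0.151 and 0.165, within 0.00135 to 0.165). Mature pollen genes counted 7 higher, 3 lower and 14 not called, with 2 lower when adjusted over the list alone (median 0, camera adjusted p = 0.6), and male germline genes 1 higher and 7 not called (median 0, camera adjusted p = 0.82). Female gametophyte genes counted 1 higher, 2 lower and 3 not called (median -0.20, camera adjusted p = 0.6): EC1.4 (AT4G39340), of the egg cell, had 2.001 ± 0.274 CPM in gynoecia and no count in leaf, and AGL62 was at least 22.9-fold lower.

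All 37 photosystem genes were lower in gynoecia than in leaf (median -3.86, camera adjusted p = 6.72e-13, and 0.119 with an estimated correlation, within 1.73e-18 to 0.119 over the camera alternatives), beside 0.928% of counts on chloroplast genes against 5.90% in leaf. All 16 Calvin cycle genes were lower (median -4.30, camera adjusted p = 1.51e-07, and 0.0133 with an estimated correlation), with RBCS1A 17.2-fold lower and RBCS2B (AT5G38420) 158-fold, the latter with reads that near-identical copies may share. All 12 defence markers were lower (median -4.81, camera adjusted p = 1.37e-05, and 0.0131 with an estimated correlation): PR2, PR1 and PAD3 had no count in gynoecia and were at least 2036-fold, 781-fold and 553-fold lower. Flavonoid genes counted 8 higher and 3 lower (median 2.25, camera adjusted p = 0.0741), with the flavonol regulator MYB12 (AT2G47460) at least 101.2-fold higher and LDOX (AT4G22880), of anthocyanin synthesis, at least 23.4-fold lower. Auxin genes counted 11 higher, 6 lower and 1 not called (median 2.01, or 1.865 at the bound, camera adjusted p = 0.177): TAA1 (AT1G70560), of auxin synthesis, was 17.1-fold higher and PIN7 3.33-fold lower. Gibberellin genes counted 7 higher, 1 lower and 4 not called (median 0.46, camera adjusted p = 0.103, but 0.0457 with library totals, within 0.0457 to 0.176 over the camera alternatives), with the DELLA gene RGL2 (AT3G03450) 14.5-fold higher. Jasmonate genes counted 6 higher, 11 lower and 3 not called (median -0.365, camera adjusted p = 0.217), which turned to 10 higher and 9 lower with library totals. Housekeeping genes counted 1 higher, 5 lower and 1 not called, with 2 higher when adjusted over the list alone (median -0.78, camera adjusted p = 0.0947): ACT7 was 1.23-fold higher, ACT2 4.76-fold lower, and PP2AA3 stood at 96.5 ± 2.79 and 90.6 ± 2.38 CPM (adjusted p = 0.054). PP2AA3 was called higher with DESeq2 size factors (0.0494), upper quartile factors (0.000102), no filter (0.0343), the libraries of both tissues alone (0.00414), FPKM (3.21e-08 to 7.85e-08) and library totals (6.63e-22). It was also called without female replicate 2 (0.0174), leaf replicate 2 (0.0266) or male replicate 1 (0.0425) or 2 (0.046), within 6.63e-22 to 0.15 outside the test against a 2-fold change.

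Of 20827 genes tested, 17192 (82.5%) differed between gynoecium and leaf by edgeR, 8869 higher and 8323 lower in gynoecia, of which 5534 and 5335 by at least 2-fold. The largest changes included the cytochrome P450 gene CYP706A3 (AT5G44620), at 371 ± 4.94 CPM in gynoecia and no count in leaf. The cellulase gene CEL2 (AT1G02800) stood at 340.2 ± 7.36, the homeobox gene AT2G33880 at 206 ± 5.3 and ERL2 (AT5G07180), a receptor kinase of the ERECTA family, at 196 ± 5.70 CPM, all with no count in leaf. The channel gene CNGC11 (AT2G46440) had 282 ± 14.1 CPM in leaf, the ankyrin repeat gene ANK (AT5G54610) 239 ± 2.6 and the receptor-like kinase gene RLK1 (AT5G60900) 184 ± 2.52, all with no count in gynoecia. The share of calls that were higher was 51.6% with TMM and 67.3% with library totals, which moved the median of all genes by 0.55.

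**Figure D2:**
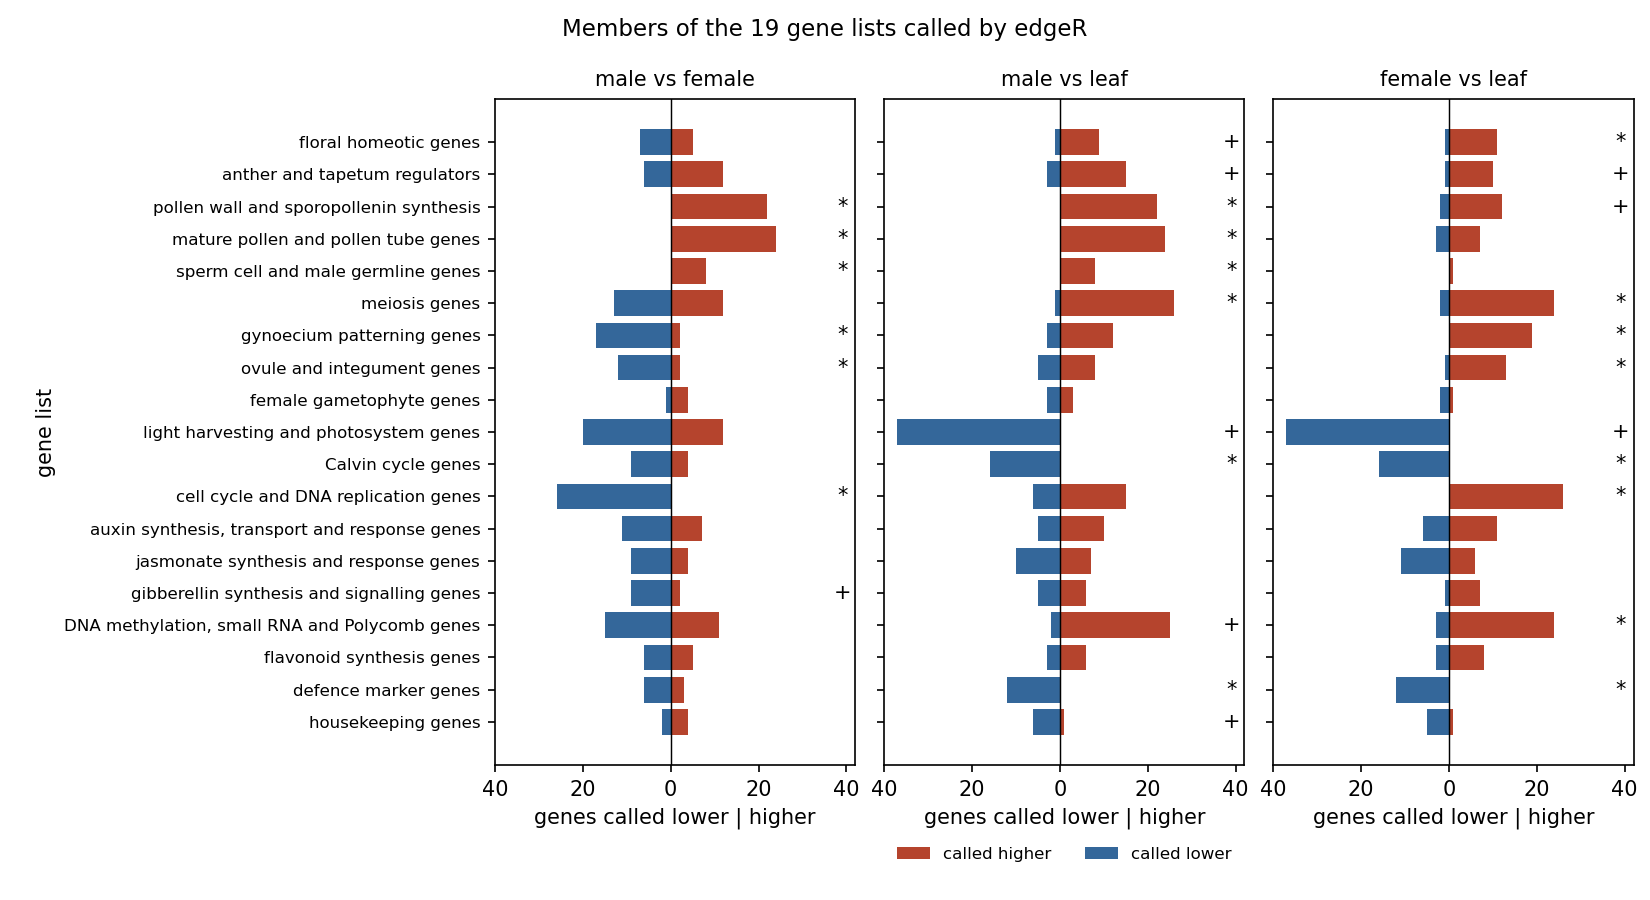
Number of tested members of each of the 19 gene lists called higher (right) or lower (left) by edgeR in the comparisons of male with female, male with leaf and female with leaf libraries. An asterisk marks a list whose camera call holds with an estimated correlation and a plus sign one whose call is then lost; all 26 cell cycle genes are lower in stamens than in gynoecia and all 37 photosystem genes are lower in both floral organs than in leaf, while the housekeeping list turns with the scaling between stamens and gynoecia.

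Gene families, formed from words in the gene descriptions, add groups outside the fixed lists. Of 31 families tested, 9 differed between stamens and gynoecium, 5 between stamens and leaf and 4 between gynoecium and leaf by camera. F-box proteins, which choose targets for ubiquitin, were the largest group that was higher in stamens: 248 of 338 were higher and 58 lower than in gynoecia (median 4.42, or 3.13 at the bound, adjusted p = 2.18e-08), and 275 higher and 41 lower than in leaf (median 7.28, or 2.62 at the bound, adjusted p = 2.19e-09). Their calls held with an estimated correlation (adjusted p = 0.0111 and 0.00742), and those of the other families did not. The F-box gene AT1G80470 had 63.5 ± 1.04 CPM in stamens and no count in the other tissues. Another F-box gene, DAF1 (AT3G62230), had 243 ± 3.23 CPM in stamens and no count in leaf.

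Against gynoecia, stamens also had more transcripts of genes described as S-locus or self-incompatibility genes, many of them S-locus lectin kinases (22 of 29 higher and 3 lower, adjusted p = 0.00696, and 0.0975 with an estimated correlation). Genes with invertase/pectin methylesterase inhibitor in their description were called in the same direction (40 of 60 higher and 19 lower, 0.0241, and 0.192). This description also covers the pectin methylesterase genes VGD1 and VGDH1, so the family is not made of inhibitors alone. Genes with ubiquitin in their description were called higher too (162 of 269 higher and 59 lower, 0.0241, and 0.0502). The F-box and ubiquitin families share members such as AT4G22390, so their calls are not independent. AT2G04115, a self-incompatibility protein gene, was at least 112-fold higher, and AT3G62180, of the invertase/pectin methylesterase inhibitor description, at least 1090.0-fold. Ribosomal proteins were lower in stamens in 251 of 305 cases and higher in 28 (median -0.97, adjusted p = 1.41e-12, and 0.339 with an estimated correlation). Genes with histone in their description (65 of 102 lower and 28 higher, 0.00647, and 0.389), pentatricopeptide proteins (117 of 234 lower and 61 higher, 0.0163, and 0.192), kinesins (19 of 29 lower and 8 higher, 0.0356, and 0.389) and chlorophyll genes (15 of 24 lower and 5 higher, 0.0356, and 0.389) were called lower too. The kinesin gene AT4G26660 was 13.8-fold lower, and CLH1 (AT1G19670), a chlorophyllase, 4.44-fold lower, whereas LHB1B1 (AT2G34430), of the light-harvesting complex, was 5.42-fold higher.

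Against leaf, stamens had fewer transcripts of receptor-like kinases (59 of 94 lower and 32 higher, adjusted p = 0.00564, and 0.124 with an estimated correlation), WRKY factors (31 of 53 lower and 16 higher, 0.0122, and 0.0821) and chlorophyll genes (23 of 24 lower and 1 higher, 4.56e-08, and 0.0821). The receptor-like kinase genes CRK6 (AT4G23140) and CRK4 (AT3G45860) had 165 ± 2.47 and 107 ± 7.55 CPM in leaf and no count in stamens, while WRKY31 (AT4G22070) had 75.9 ± 0.285 CPM in stamens and no count in leaf. Genes with invertase/pectin methylesterase inhibitor in their description, enzymes among them, were higher in 40 of 60 cases and lower in 14 (0.0122, and 0.0821). Gynoecia had more transcripts than leaf of ribosomal proteins (228 of 305 higher and 53 lower, adjusted p = 0.00011, and 0.559 with an estimated correlation), genes with histone in their description (70 of 102 higher and 17 lower, 0.000909, and 0.322) and kinesins (20 of 29 higher and 5 lower, 0.0149, and 0.338), and fewer of chlorophyll genes (20 of 24 lower and 2 higher, 0.00011, and 0.307). POK2 (AT3G19050), a kinesin that guides the division plane, had 4896 counts in gynoecia against 1 in leaf, in replicate 3, a ratio of 2920 (exact 95% interval 524 to 115000), and ATK5 (AT4G05190), a spindle kinesin, was at least 143-fold higher. No called family changed its direction with another scaling.

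Genes highest in 1 tissue passed the test and stood at least 2-fold above both other tissues. There were 3904 in stamens, 2145 in gynoecium and 3549 in leaf, 9598 in all, and 1499, 198 and 219 of these had no count in either other tissue. In stamens, the multicopper oxidase-like gene sks11 (AT3G13390) had 635 ± 15.4 CPM and the phosphodiesterase gene GDPD6 (AT5G08030) 487 ± 17.5, with no count elsewhere. In gynoecium, the peptidase gene scpl47 (AT5G22980) had 34.7 ± 0.733 CPM with no count elsewhere, and SKS1 (AT4G25240) had 45.2 ± 0.785 CPM against 0.101 ± 0.0936 in stamens. The stamen counts of SKS1 were 0, 2 and 3, and without male replicate 3 its log2 change against gynoecia went from -8.73 to -9.43. In leaf, ACD6, CRK6, BG3 and CRK4 had no count in either floral organ. With library totals in place of TMM, 3667 genes were highest in gynoecium.

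Both floral organs were called higher than leaf for 6392 genes, 3608 of them by at least 2-fold in each, where independent lists of the same sizes would share 4437. The pollen coat gene GRP17 and the receptor kinase gene EMS1 were among them. GRP17 stood in gynoecia at 0.191% of its stamen level, where carry-over of a single stamen tissue stays open. Both floral organs were lower than leaf for 5997 genes, against 3151 for independent lists. Both changes are taken from the same leaf level, so even unrelated tissues would share more than independent lists do. The leaf libraries also serve both comparisons. Since 3 libraries cannot be divided into separate control groups of at least 2, part of the excess may come from shared controls. In 20 simulations of unchanged groups around the means of the same leaf libraries, edgeR called a mean of 0 genes in each comparison and 0 higher in both, which leaves out the chance of the leaf libraries and so does not measure that part. In 20 simulations added after seeing the data, with the leaf libraries simulated too, edgeR called 0 higher in both, and at an unadjusted p under 0.05 a mean of 97.9 were, against 10.4 for independent lists. Both sets of simulations hold unchanged groups, unlike these data, and do not measure the effect of a common leaf level.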

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

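The tests of the other splits of the libraries were planned, and the counts of genes that went opposite ways were looked at only after the comparisons were seen. Against leaf, 1612 genes were higher in stamens and lower in gynoecium, and 1146 were lower in stamens and higher in gynoecium. These stand out because the 2 floral organs moved in opposite directions under the same contrast. By edgeR all of them also differed between stamens and gynoecium, which their selection nearly fixes and which adds no evidence. At least 2-fold each way were 520 and 188 of them. Independent lists of the same sizes would share 4164 and 3358. Both changes are taken from the same leaf level, which makes opposite directions rarer for any tissues, so these figures are no baseline. With library totals in place of TMM the counts were 1028 and 1743, and with upper quartile factors 1395 and 1416, so which direction holds more genes depends on the scaling. With limma-voom the counts were 3082 and 1237, and the cause was not tested.

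Other splits of the same libraries were counted for each result. Between stamens and gynoecium, 17773 genes were called against at most 0 in another split, which 1 of the 10 splits reached. Between stamens and leaf 18305 were called against 0, and between gynoecium and leaf 17192 against 0, each in 1 of 10. Gene lists gave 7 against 8 between stamens and gynoecium (8 of 10 splits as large), 11 against 10 between stamens and leaf (1 of 10) and 11 against 11 between gynoecium and leaf (2 of 10). Families gave 9 against 6 (1 of 10), 5 against 6 (2 of 10) and 4 against 4 (2 of 10). In these comparisons 10 splits are too few for a share under 0.05. Splits that called 0 genes still called up to 8, 10 and 11 lists. Each of the other splits divides the tissues unevenly between the groups, so part of the real contrast stays in it. Camera weighs the genes of a list against all other genes and can call lists and families from that part. The numbers of lists and families called in these splits therefore cannot tell whether such calls depend on the real groups. For the genes highest in 1 tissue the values were 9598 against a highest other value of 3077. For those higher in both floral organs than in leaf they were 6392 against 0. In each case only the real split was as large, among 100 drawn from 280 possible ones. The other splits mix tissues that differ widely, so fewer genes called in them were nearly fixed in advance, and no conclusion on chance is drawn. They also say nothing on whether the libraries of a tissue come from separate plants.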

How the results depend on the processing

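Library totals, the fits without organelle or overlapping genes, other scalings for genes higher in both floral organs, and all alternatives for genes that went opposite ways were chosen after seeing the data, and the other alternatives were planned. Of 213 named gene results, 191 kept direction and call under all alternatives, and of 5048 values 4966 did, 33 lost a call, 49 gained one and 0 reversed. Of 57 list results 22 did, and of 912 values 867 did, 13 lost a call, 28 gained one and 4 reversed. Single genes that lost a call, such as RBCS1A, ETT, AMS, STK and DME, are given with their values beside the comparisons.

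The test against a 2-fold change asks for more than any difference and so calls fewer genes: 8541 between stamens and gynoecium (5401 higher, 3140 lower), 10930 between stamens and leaf (6505 and 4425) and 9828 between gynoecium and leaf (4930 and 4898). Asking for 4-fold above both other tissues left 5729 genes highest in 1 tissue (901 in gynoecium, 1919 in leaf). No fold minimum gave 17719 (6588 in stamens, 5134 in gynoecium, 5997 in leaf), and 2-fold in both floral organs left 3608. For the following the cause was not tested. With limma on log2 FPKM, 5410 genes were lower in gynoecium than in leaf with 1 added and 5390 with 0.1 added, and at least 2-fold lower were 3029, 3479, and 3088 without a filter. With limma-voom, 3082 genes were higher in stamens and lower in gynoecium than in leaf. With library totals, 5777 genes were at least 2-fold lower in stamens than in gynoecium, 3667 were highest in gynoecium, 1028 and 1743 went opposite ways in the floral organs, and 9 families differed between gynoecium and leaf. Without overlapping genes, 8 families differed between stamens and leaf.

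The self-contained test fry asks whether a list moves, on balance, one way, and called 16, 19 and 19 lists in the comparisons of male with female, male with leaf and female with leaf. Between stamens and gynoecium it gave the direction up where camera gave down for homeotic genes (adjusted p = 9.73e-09), meiosis genes (1.41e-07), jasmonate genes (0.00084) and gibberellin genes (0.000126). With an estimated correlation 6 lists differed between stamens and leaf, and 2 families in all, 1 between stamens and gynoecium, 1 between stamens and leaf and 0 between gynoecium and leaf. At an unadjusted p under 0.05 the genes called by edgeR numbered 17865, 18361 and 17275 in the same order of comparisons.

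Leaving out each replicate gave 17560 to 18095 genes between stamens and gynoecium, 18185 to 18565 between stamens and leaf, and 16972 to 17401 between gynoecium and leaf. It gave 5 to 8 families between stamens and leaf, with 8 without female replicate 1 and without male replicate 3. Of 213 gene results 209 kept their call in all of these, and the gibberellin list lost its call between stamens and gynoecium without male replicate 1. With the replicate number as a replicate block, 17644, 18204 and 17100 genes were called, and 0 of the named genes and lists changed. Fewer than 3 counts per library, 0.126 to 0.229 CPM, could not be told from 0.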

Other observations

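The tests of carry-over, of shared bases and of low leaf expression were chosen only after the results were seen, as were the genes named here. Some abundant genes moved away from leaf in opposite directions in stamens and gynoecium, and no function was tested for being common among them. The peptidase gene scpl48 (AT3G45010) stood at 1537 ± 42.3 CPM in stamens, 5.42 ± 0.424 in gynoecium and 71.7 ± 4.30 in leaf. PAL1 (AT2G37040), the first enzyme of phenylpropanoid synthesis, stood at 1211 ± 18.7, 26.99 ± 1.67 and 67.8 ± 2.72 CPM, the sucrose carrier gene SUC1 (AT1G71880) at 778 ± 21.5, 47.8 ± 1.23 and 293 ± 6.38, and the amino acid carrier gene LHT2 (AT1G24400) at 592 ± 6.71, 1.82 ± 0.508 and 12.1 ± 1.004. In the other direction, the expansin gene EXPA6 (AT2G28950), which loosens cell walls, stood at 80.7 ± 2.03 CPM in stamens, 810.2 ± 23.6 in gynoecium and 234 ± 8.29 in leaf. The cuticle gene BDG1 (AT1G64670) stood at 2.14 ± 0.371, 136 ± 2.23 and 8.87 ± 0.0355, the aquaporin gene PIP2;8 (AT2G16850) at 6.61 ± 1.26, 104 ± 2.78 and 18.1 ± 0.433, and the lipid transfer gene LTPG1 (AT1G27950) at 49.0 ± 2.14, 234 ± 7.24 and 101.1 ± 5.63. The LTPG1 call between stamens and leaf ended in the test against a 2-fold change (adjusted p = 0.118, within 1.02e-76 to 0.118 over its alternatives).

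Many genes with clear counts in both floral organs had no count at all in leaf. Of 10262 genes with at least 500 counts in each floral organ, 141 were at 0 in all 3 leaf libraries (1.37%), among them AG, AP3, PI, AGO9, EMS1 and ERL2, and also genes not tied to flowers, such as the clock gene CCA1 (AT2G46830), the biotin synthesis gene BIO1 (AT5G57590), the splicing factor gene AT3G04160 and the DNA damage gene DDB2 (AT5G58760). There were 19 genes at 0 in gynoecium alone by the same rule and 4 in stamens alone. Another 43 lay at 1 to 20 leaf counts. Low leaf expression sampled at this depth cannot be told apart from silence, since all levels far below 1 count read as 0. Reads counted for an adjacent gene would raise the neighbours in leaf, and their median differed by -0.12 (95% interval -0.41 to 0.18) from that beside genes with 21 to 200 leaf counts, and a deleted stretch of the genome would put these genes side by side, which held for 2 of 141 (1.4%). The tables argue against many reads moved to neighbours and against a deletion over adjacent genes. A few moved reads, or the loss of single genes, would not show in these values and were not tested. Low expression and silencing in leaf stay open, as does a filter applied by the authors in leaf alone, which was not tested.

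Genes whose exons lie inside another gene model had hardly any counts. Of 349 protein-coding genes whose exon bases all lie in another annotated gene, 347 were at 0 in every library (99.4%), against 16.5% of genes with no shared base. Short gene models alone would leave genes of the same length with no shared base at 0 as often, and 44.5% of those were, which argues against them as the whole cause. Reads on shared bases left out by the counting should raise the share at 0 with the share of bases shared. It first fell, to 5.62% with up to 50% shared, and then rose to 51.6% with 50 to 90% and to 91.6% above that, so this explanation stays open. A count of 0 may reflect the gene model for such genes, which in the lists may hold for ROXY1, GEX2, MYC2 and F3H, with over 90% of their bases shared, and less surely for ALC (84.5%). No biological explanation was tested.

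Of 56 genes chosen for at least 20000 counts in stamens and at most 3 in leaf, 8 had no count in gynoecium and the others small shares of their stamen level. Carry-over of stamen RNA or reads would bring all of them at 1 share, no higher than the 0.00449% that AT3G01270 (125557 counts in stamens, 0 in gynoecium) allows, and in 44 of the 56 (78.6%) the low end of the exact 95% interval, adjusted for all 56, lay above that limit, which argues against it as the whole cause. The median share was 0.127% and the highest 8.64%, and MS2 had 83252 counts in stamens and 4 in gynoecium where ATA27 had 261302 and 1083. Expression in the gynoecium itself, or carry-over of a single stamen tissue with part of these transcripts, may account for the difference and stays open.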
